A study of Xenopus laevis with 5 samples.

How the data were processed

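RNA from Xenopus laevis ectodermal explants was measured on 5 Affymetrix arrays, 2 of explants with an inducible zic1 and 3 of control explants with beta globin. Per the labels' protocols, embryos with 2 cells received a zic1 whose activity a hormone switches on, or beta globin, and noggin in both cases. Noggin is an inhibitor of BMP signals that turns ectoderm neural. Explants were cut at stage 9 and kept to an age that equals stage 12. Cycloheximide, which stops protein synthesis, was given for 30 min before dexamethasone, the hormone that releases the injected zic1 protein, and explants were taken 3 h later. From each sample 2 µg of total RNA was labelled with biotin. The labels name the arrays of each group as biological replicates and do not say which embryos or days they came from, so the p-values measure the spread between these arrays.

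The submitters' processing notes name GCOS and RMA, without versions and without saying which step each did. The deposited values are linear ratios: in all 15571 probe sets with 5 values, the median over the 5 arrays was exactly 1 (tolerance 0), and the median of each array was 1. That centring was found from the values, since no source used here states it. The absolute signal was not kept, so no probe set could be set against background or against another, and the number of arrays limits the precision. The table holds 15572 probe sets, of which 81 Affymetrix controls were left out. 1 further probe set had no values in the zic1 arrays, which left 15490 tested.

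Gene symbols came from the platform annotation, with 2 updated through the gene identifier. Of 15491 probe sets, 9304 had 1 symbol, 195 had several and 5992 had none here, and 9227 of those with 1 symbol matched the gene table. No genome coordinates are given, because the build of that table is not tied to these arrays. The suffixes .L and .S, or -a and -b in older symbols, mark the paired gene copies of this allotetraploid frog, whose sequences are close enough to share signal on short probes.

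The zic1 and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on log2 of the ratio, with Benjamini-Hochberg adjustment over 15490 probe sets and a threshold of 0.05. The fit had 3 residual and 2.29 prior degrees of freedom. The design written before the data were examined took the values for array signals. Ratios needed log2 without a pseudocount and left no dim probe sets to filter, no intensity trend to fit and no brightest probe set to choose. Those filters and the trend were therefore not run, and a gene's value in the list tests was the mean log2 ratio over its probe sets. A second count took probe sets at least 1.5-fold apart, with no overlap of the groups and an unadjusted p under 0.05. The centring of each probe set does not enter the differences between arrays. Values are given as log2 difference ± SE, zic1 minus control, and folds with 95% confidence intervals.

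The 24 gene lists were fixed before the data were examined and were tested with camera (limma) on 7530 genes with a preset correlation of 0.01, adjusted over the 24 lists. Each was also tested with an estimated correlation and with fry. Named genes followed a rule of the same date: the injected genes and Zic family, the 15 largest rises and 10 largest falls past the threshold with an informative symbol, up to 4 members of each list by moderated t, all members of the list of reported Zic1 targets, and actin genes. Other genes are said to have been chosen after their values were seen. On data simulated for this comparison over 15490 probe sets, 64 of 100 probe sets changed by 1 on the log2 scale and 95 of 100 changed by 2 were recovered, with 7 false calls. Variances were drawn from the limma fit to the real arrays, and the simulated arrays held no grouping beyond zic1 and control. These rates may therefore not hold for the real arrays. The simulated genes varied independently, and all genes of 1 list were shifted by 0.5. That list was called, and 0 of the unchanged lists. This does not test lists of correlated genes, and the correlation estimated in the real lists reached 0.465, for ribosomal genes.

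Alternatives were median centring, cyclic loess, array weights, the replicate number as a block, each array left out in turn, another threshold, no variance moderation, pseudocounts of 1 and 16, a fold threshold of 2, and other set tests. A robust prior, and 2 sets of arrays as a block, were added after the values were seen. The first set, zic1 replicate 1 with control replicates 1 and 2, came from exactly equal values that these 3 arrays shared; the second is the 2 arrays left over, which shared no more equal values than other pairs. The grouping was found in the values and is not stated by the labels. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.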

Results

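Transcript levels were measured in explants of frog ectoderm made neural with noggin, with an inducible zic1 in 2 samples and beta globin in 3. Zic1 is a zinc-finger transcription factor of the neural plate and its border. Protein synthesis was blocked before zic1 was activated, a design meant to address which transcripts change without new protein. Every sample received dexamethasone, so any effect of the injected zic1 before the block cannot be separated in this comparison. Each value is a probe set's level relative to its own median over the 5 arrays, and the number of arrays limits the precision.

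Zic1 transcript was higher in the explants injected with zic1. Probe sets of the injected genes may lie outside the injected coding part, and then they do not measure the injected RNA. The zic1.S values can therefore hold injected RNA, the embryo's own transcript or both. The zic1.S probe set with the larger difference read 5.28 and 5.07 in the zic1 arrays and 1.00, 0.965 and 0.699 in the controls, a log2 difference of 2.56 ± 0.17 (adjusted p = 0.0134, limma), which turned to -0.23 after cyclic loess of the ratios. The loess curve ran here along the mean log2 ratio, which itself holds the group difference. A sign that it turned, here or below, therefore does not settle a direction. A second zic1.S probe set rose by 0.93 ± 0.11 (adjusted p = 0.0376, limma). Zic5.S rose by 1.70 ± 0.21 and zic2.L by 0.91 ± 0.12. The probe sets of zic2.S (0.75 and 0.73) and zic4.L (0.69) did not pass the threshold. Noggin, which both groups received, differed by 0.12 ± 0.21 for nog.L (adjusted p = 0.795). The globin probe sets lay between -0.12 for hbd.S and 0.10 for hba1.S, so they gave no sign of the beta globin injected in the controls.

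In the zic1 explants 170 probe sets were higher and 49 lower than in controls, 219 of 15490 past an adjusted p of 0.05. The largest rises in named genes past the threshold were in gsta1.L, a glutathione S-transferase, and ptgds-b, a prostaglandin D synthase of the lipocalin family. Gsta1.L was 13.4-fold higher (95% interval 9.71 to 18.6) and ptgds-b 12.7-fold higher (7.24 to 22.3). Transcription factors followed: myod1.S, the muscle determination factor, rose by 2.86 ± 0.18, snai1.S, a zinc-finger repressor of neural crest and mesoderm, by 2.76 ± 0.20, and vegt.L, a T-box factor of endoderm and mesoderm, by 2.49 ± 0.18. Hesx1.S, a homeobox gene of the forebrain, rose by 2.15 ± 0.08, and hes5.5.S, of a family of Notch-responsive repressors, by 2.34 ± 0.27. Other hes5.5.S probe sets lay at 1.41, past the threshold, and 0.10, not past it. After cyclic loess of the ratios the differences of gsta1.L (-0.28), myod1.S (-0.0058), snai1.S (-0.20) and hesx1.S (-0.56) turned negative and did not pass.

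Other large rises, of which those of glipr2.S, thop1.L, celf3.S and prickle1.L turned after cyclic loess, were in glipr2.S (2.72), the apelin receptor aplnr.S (2.68), the peptidase thop1.L (2.66), the RNA-binding celf3.S (2.16), and both copies of prickle1, a planar polarity gene (2.11 for prickle1.S and 2.06 for prickle1.L). One probe set of anxa5.S rose by 2.33 ± 0.19, while 5 others of that symbol lay between -0.68 and -0.03, so the symbol does not give the gene 1 direction. The largest falls past the threshold were in hsd3b7.L, an enzyme of bile acid synthesis (-2.84 ± 0.28), cdc42se2.S (-2.20 ± 0.13), scmh1.S, a Polycomb group gene (-1.86 ± 0.15), and mfsd5.S (-1.73 ± 0.17). A second cdc42se2.S probe set rose by 0.89 ± 0.08. Further probe sets of scmh1.S (-1.08) and mfsd5.S (-0.59 and -0.16) did not pass. Smad9.S, a transducer of BMP signals, fell by 1.32, atp5pb.L by 1.22, rfc5.L by 1.09, rpl18.S by 1.04, cgl.2.S by 1.00 and tbx2.L by 0.99.

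**Figure D1:**
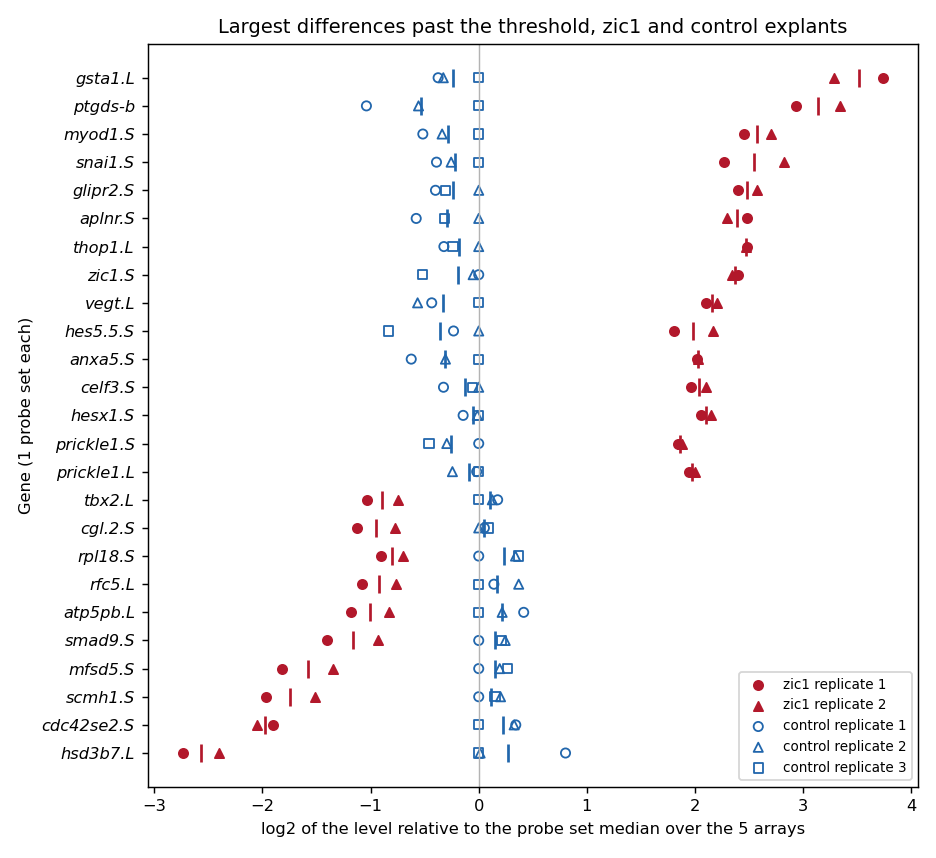
Level of each named gene relative to its probe set's median over the 5 arrays (log2, horizontal axis) for the 15 largest rises and 10 largest falls past the threshold; symbols are single arrays and vertical ticks are group means. The 2 zic1 arrays lie on 1 side of all 3 controls in every gene shown. Zic1.S, for example, read 5.28 and 5.07 against 1.00 or less (ratio). Its difference turned to -0.23 after cyclic loess of the ratios, which runs along the mean log2 ratio and so holds the group difference itself.

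Of the 219 probe sets, 97 were at least 2-fold higher and 13 at least 2-fold lower, and 90 had no single gene symbol. The rest named 88 genes higher and 33 lower. The second count, of probe sets at least 1.5-fold apart without overlap at an unadjusted p under 0.05, held 672 higher and 456 lower; it was 658 in all without zic1 replicate 1, 869 without control 2, and 1329 to 1355 without each other array. The groups did not overlap in 39.3% of probe sets, where chance gives 20%. The adjusted calls depended on every array: limma called 0 probe sets without either zic1 array (1467 and 2483 at an unadjusted p under 0.05), 21 without control 1, 5 without control 2 and 207 without control 3, only 99 of these among the 219, and cyclic loess of the ratios also left 0 (3331 unadjusted). Array weights gave 584 higher and 351 lower, and with the 2 sets of arrays as a block 37 passed, 34 of them among the 219.

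**Figure D2:**
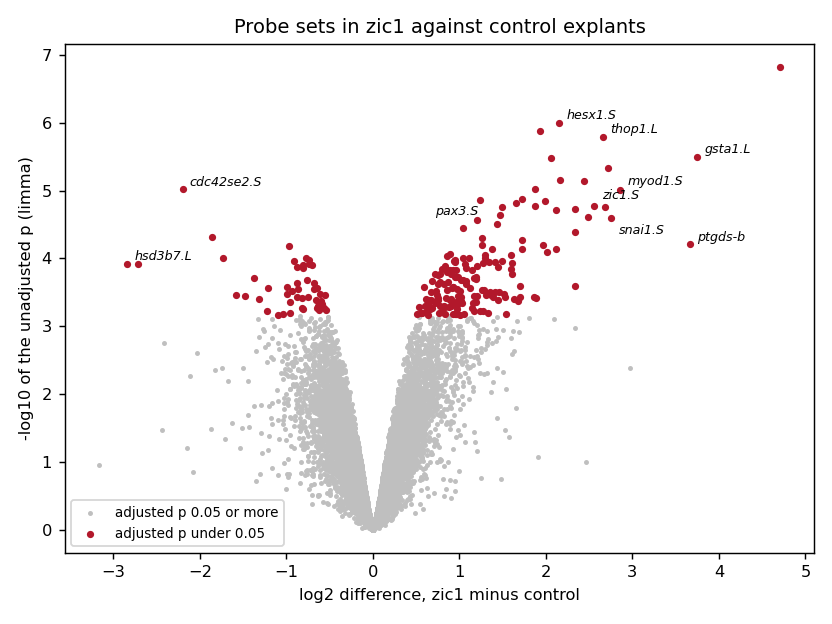
Log2 difference, zic1 minus control (horizontal axis), against -log10 of the unadjusted limma p (vertical axis) for 15490 probe sets; red points are the 219 past the adjusted threshold, 170 higher and 49 lower. The values are as deposited. After cyclic loess of the ratios 0 probe sets passed and zic1.S, marked here at 2.56, lay at -0.23. That curve runs along the mean log2 ratio, which itself holds the group difference.

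Genes that other work has reported as targets of Zic1 rose as a list (camera adjusted p = 8.05e-05; adjusted p = 0.403 with an estimated correlation), with 5 of 28 probe sets past the threshold, 8 adjusted over the list alone. These were ptgds-b, snai1.S, pax3.S (1.46 ± 0.11), pax3.L (0.67 ± 0.08) and crabp2.L, which binds retinoic acid in the cytoplasm (1.87 ± 0.13), and cyclic loess turned all but ptgds-b of them. The other pax3.L probe sets lay at -0.50, 0.14 and 0.20, not past the threshold. Aqp3.L, of the water channel family that the study reported from these samples, differed by 1.32 ± 0.28 without passing (adjusted p = 0.0874, limma). It read 1.58 and 2.99 in the zic1 arrays, and the copy aqp3-a differed by 0.06 (adjusted p = 0.691). The presence of aqp3 makes the list less than independent. Aldh1a2.L, which makes retinoic acid, differed by 0.49 ± 0.07 (adjusted p = 0.0557, limma), and by 0.19 in another probe set (adjusted p = 0.298). Probe sets of en2, wnt1, wnt3a, wnt4 and wnt8b lay between -0.14 for wnt4.L and 0.02 for en2.S. The list of injected genes and the Zic family, which holds zic1 itself, also passed (adjusted p = 7.21e-04; 0.403 as the adjusted p with an estimated correlation), with 4 of 15 probe sets past the threshold and 7 adjusted over the list alone, and both lists fell short after cyclic loess (adjusted p = 0.351 and 0.0518).

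The neural plate and its border rose as lists. Pan-neural genes had a median log2 difference of 0.23 (camera adjusted p = 3.96e-08; adjusted p = 0.282 with an estimated correlation), with 3 of 35 probe sets past the threshold and 10 adjusted over the list alone. These were 1 probe set of sall1.L (1.93 ± 0.08, but -0.45 after cyclic loess), zic5.S and zic2.L. The other sall1.L probe sets lay at 0.44 and 0.09 and did not pass. Zic5.S and zic2.L were also calls of the Zic family list. Border and neural crest genes had a median of 0.15 (adjusted p = 5.43e-04; adjusted p = 0.282 with an estimated correlation, and 0.109 after cyclic loess), with 5 of 44 past the threshold and 10 adjusted over the list alone, among them snai1.S and pax3.S. The 5 were snai1.S, pax3.S, 1 probe set of pax3.L and both zic1.S probe sets. All of them had passed in the lists of reported targets or of the Zic family above. The rise of the border list is therefore independent neither of those lists nor of the injected gene. Tfap2b.L (0.59) and snai2.L (0.60) did not pass. Anterior neural, eye and placode genes had a median of 0.11 (adjusted p = 3.02e-04; adjusted p = 0.389 with an estimated correlation), with hesx1.S, hesx1.L (1.49 ± 0.10, but -0.12 after cyclic loess) and 1 of 8 probe sets of pax2.L (0.67 ± 0.09) higher and tbx2.L lower. The rest of pax2.L lay between 0.11 and 0.49 and did not pass. Adjusted over the list alone, 6 probe sets were higher and 1 lower. Tested by fry, which asks whether a list moves 1 way on balance, these 3 lists passed (adjusted p = 0.0400 each) and the other 21 did not.

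Midbrain, hindbrain and posterior genes passed narrowly (median 0.02, adjusted p = 0.04998; adjusted p = 0.604 with an estimated correlation), with 1 of 47 probe sets past the threshold and 4 adjusted over the list alone. Their mean was 0.13 in 1 set of arrays and -0.02 in the other. That call was lost without zic1 replicate 2 (adjusted p = 0.102), control 1 (0.0893) or control 2 (0.304), and with the sets as a block (0.109). The posterior probe set past the threshold was of pax2.L and was already counted in the anterior list. Neuronal differentiation genes had a median of 0.06 (camera adjusted p = 0.00644, and 0.469 with an estimated correlation). Of their 35 probe sets 0 were past the threshold, and 2 when adjusted over the list alone. Elavl3.L, an RNA-binding protein of early neurons, differed by 1.66 ± 0.25 (limma adjusted p = 0.0512).

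Among signalling lists, Notch (median 0.20, adjusted p = 7.21e-04), Wnt (0.08, adjusted p = 9.00e-04), cell adhesion (0.11, adjusted p = 1.93e-04) and retinoic acid genes (0.02, adjusted p = 0.0108) passed with the preset correlation. With an estimated correlation their camera adjusted p were 0.297, 0.403, 0.403 and 0.458. The correlation itself was estimated at 0.0119 for the Notch list and -0.00987 for the border list, against the preset 0.01. Correlated genes therefore do not account for the lost calls of those lists. Their lists held 6, 4, 5 and 4 higher probe sets and 0 lower when adjusted over each list alone. In the Notch list the ligand jag1.L rose by 1.39 ± 0.17, while hes7.1.L (1.60), hes1.S (1.39) and notch1.S (1.00) did not pass. Another hes7.1.L probe set differed by 0.22. Wnt8a.L rose by 1.04 ± 0.08 (-0.015 after cyclic loess) and sfrp2.S, a secreted Wnt antagonist, by 0.78 ± 0.08. The tight-junction genes cldn5.S (1.08 ± 0.12) and cldn5.L (0.83 ± 0.08) and the ephrin receptor epha4.L (0.92 ± 0.12) rose. Another epha4.L probe set differed by 1.09 without passing (adjusted p = 0.0512, limma). The retinoic acid call was lost without control 2 (camera adjusted p = 0.0595), after cyclic loess (0.129) and with all probe sets of a gene kept apart (0.0685). In that list 2 of 33 probe sets were past the threshold over all probe sets, ptgds-b and crabp2.L, both already counted among the reported targets. Its mean was 0.26, well above its median. FGF and ERK genes (adjusted p = 0.134; median -0.0022 and mean 0.0905) and Hedgehog genes (adjusted p = 0.0585) did not pass, though fgfr2.L rose by 1.14 ± 0.12. The Hedgehog list passed without control 1 (adjusted p = 0.0398), without control 3 (0.0233) and with array weights (0.0339). Of these 2 lists, 5 FGF and ERK probe sets and 0 Hedgehog probe sets passed when adjusted over the list alone.

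BMP signalling genes did not pass as a list (median -0.10, adjusted p = 0.139), and 0 of 52 probe sets were past the threshold, also when adjusted over the list alone. That list does not hold smad9.S, whose fall passed. Szl.L (-1.35), szl.S (-1.27), ventx1.1.L (-0.74) and smad6.L (-0.61), all induced by BMP signals, did not pass. With the replicate block, which left 1 residual degree of freedom, all of them passed (limma adjusted p from 0.0063 to 0.0486). With the sets as a block none did (limma adjusted p from 0.0992 to 0.168). A second ventx1.1.L probe set differed by 0.12, the other way, without passing.

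Mesoderm, notochord and muscle genes rose as a list (median 0.05, adjusted p = 1.04e-04; adjusted p = 0.489 with an estimated correlation), with 6 of 76 probe sets higher and 0 lower past the threshold. Adjusted over the list alone, 11 were higher and 2 lower. The 6 included myod1.S, vegt.L, foxf1.L, a forkhead gene of lateral mesoderm (1.73 ± 0.11, but -0.51 after cyclic loess), and wnt8a.L. The muscle actin gene acta1.S differed by -0.07 ± 0.09 and acta2.L by 0.02 ± 0.07. No probe set carried the symbol actc1.

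Lists for other cell types of the explant or embryo did not pass: epidermis (adjusted p = 0.883), multiciliated cells and ionocytes (0.677), endoderm (0.883) and cement gland (0.848). In the cement gland list 1 probe set was higher when adjusted over the list alone, and 0 in the others. For epidermis and cement gland the median and mean were negative while the test pointed up, and for multiciliated cells the mean alone was negative. These lists differed between single arrays. Cement gland genes averaged 0.65 (log2) in control 2 against -0.20 to 0.01 in the other arrays. Endoderm genes averaged 0.37 in control 3 against -0.14 to -0.03 elsewhere, and epidermal genes averaged -0.19 in zic1 replicate 1 and -0.16 in control 1. The endoderm gene sox17b.1.S differed by -2.04 ± 0.38 (adjusted p = 0.0711) and passed without control 3 (adjusted p = 0.0219), with the replicate block (0.00472) and with array weights, but not without any other array or with the sets as a block (0.0911). Its second probe set, at -1.68, did not pass.

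Ribosomal protein and translation genes were the only list that fell (median -0.37, camera adjusted p = 1.34e-11; adjusted p = 0.458 with an estimated correlation). They averaged -0.33 and -0.14 in the zic1 arrays and -0.01, 0.24 and 0.20 in the controls. Within the 2 sets of arrays the mean differences were -0.45 and -0.34. Of 119 probe sets, 1, rpl18.S, passed over all probe sets, and 0 adjusted over the list alone. Cell cycle genes rose slightly as a list (median 0.07, adjusted p = 0.00508; adjusted p = 0.458 with an estimated correlation), with 0 of 84 probe sets past the threshold and 7 adjusted over the list alone. That call was lost without control 3 (adjusted p = 0.0556) and with all probe sets of a gene kept apart (0.0608).

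Immediate early and stress genes passed narrowly (adjusted p = 0.0438; adjusted p = 0.4995 with an estimated correlation), with a median of -0.01 and a mean of 0.18. Jund.S (1.30 ± 0.16), zfp36l2.L, which promotes mRNA decay (1.33 ± 0.18), and dusp1.S (0.83 ± 0.11) rose. In all 3 of 52 probe sets passed, and 7 were higher and 1 lower when adjusted over the list alone. The list fell short without zic1 replicate 2 (adjusted p = 0.102) or control 1 (0.163), with the sets as a block (0.107), after cyclic loess (0.0704) and with all probe sets of a gene kept apart (0.304). Genes of the glucocorticoid response, the class that dexamethasone acts on, did not pass (adjusted p = 0.399), nor did aquaporins, channels and transporters (adjusted p = 0.281). Each of these lists had 2 probe sets higher when adjusted over the list alone, and the transporters had 1 lower. Both groups received dexamethasone, so a response to the hormone alone would cancel in the comparison.

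**Figure D3:**
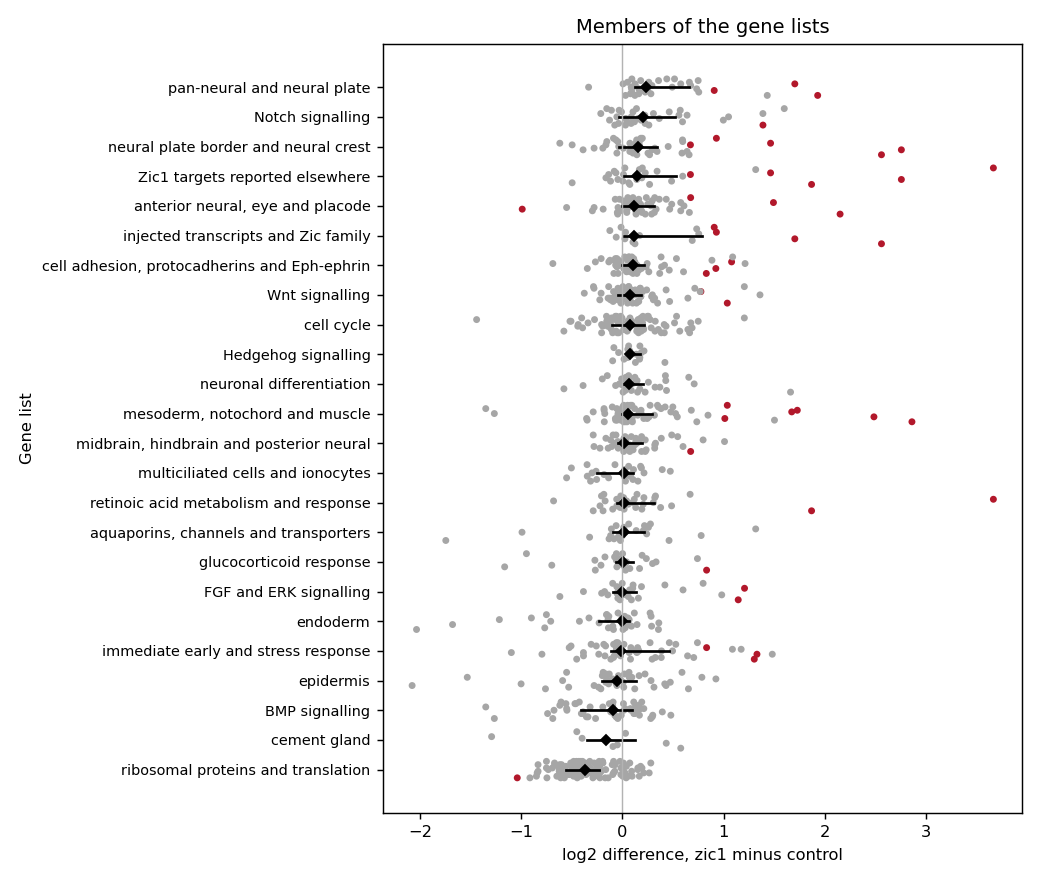
Log2 difference, zic1 minus control (horizontal axis), of each probe set in the 24 gene lists (rows); red points passed the adjusted threshold over all probe sets, diamonds are list medians over genes and black lines their quartiles. Pan-neural genes have the highest median, 0.23, and ribosomal genes the lowest, -0.37. Values are as deposited. Cyclic loess of the ratios ended the calls of 5 lists and turned no called list. Its curve runs along the mean log2 ratio, which itself holds the group difference.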

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

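The set of arrays as a block and the robust prior were chosen after the values were seen; the other alternatives were fixed before the data were examined. Of 219 probe sets past the threshold, the robust prior left 186; median centring could move nothing, each array's median being 1. The count became 935 with array weights (584 higher, 351 lower), 37 with the sets as a block, 1054 at an adjusted p under 0.10, 352 with log2(value + 16), and 0 without variance moderation (limma; 2096 at an unadjusted p under 0.05). With single arrays left out it ran from 0 to 207 (without control 3, 99 of them among the 219), and a lone zic1 array was then assumed to vary like the controls. Cyclic loess, which was planned, left 0 (3331 unadjusted) and turned the sign of zic1.S to -0.23 and of 15 other named probe sets: gsta1.L -0.28, myod1.S -0.0058, snai1.S -0.20, glipr2.S -0.13, thop1.L -0.26, celf3.S -0.32, hesx1.S -0.56, prickle1.L -0.42, sall1.L -0.45, crabp2.L -0.36, foxf1.L -0.51, hesx1.L -0.12, pax3.S -0.31, wnt8a.L -0.015 and pax3.L -0.054. It also ended the calls of 29 further named probe sets. A turned sign was counted only for probe sets past the threshold before or after cyclic loess. The loess curve runs along mean signal where signal exists, but here along the mean log2 ratio, which itself holds the group difference: 36 probe sets with a mean of at least 0.5 had a median difference of 2.12 before and -0.28 after. A dependence of the differences on signal was not tested.

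The second count, 1128, ran from 658 (without zic1 replicate 1) to 1355 and was 264 at a fold of 2. The 15 lists past the threshold became 0 with an estimated correlation and 3 with fry, 13 to 15 with single arrays left out, 12 with all probe sets of a gene kept apart, and 10 after cyclic loess. The zic1.S difference of 2.56 ran from 2.40 to 2.66 with single arrays left out, past the threshold only without control 3. Every named call, 45 of 135 probe sets, was lost without either zic1 array, and 27 with the sets as a block. With the replicate block the count was 2692, with 1334 higher and 1358 lower, so the excess of rises among the calls depends on the fit; zic1.S was 2.40, 47 named probe sets newly passed, Hedgehog genes passed (adjusted p = 0.0181) and cell cycle genes did not (0.0584). That fit has 1 residual degree of freedom, and control 3, alone in its number, adds nothing to it. Deviations from the group means correlated at 0.32 for the arrays numbered 1 and 0.28 for those numbered 2, values tied to each other because 2 zic1 arrays deviate by opposite amounts. The labels do not say what a number marks, so whether it pairs the arrays stays open. Dim-probe filters, the intensity trend and the brightest probe set were not run, for want of absolute signal.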

Other observations

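The tests on chance, on equal values and on the set of 3 arrays were chosen after the values were seen; those on mesoderm transcripts, abundant transcripts and FoxO targets were written before theirs. The genes and probe sets of this paragraph and the next were chosen after their values were seen. The largest difference of all was in a probe set without a symbol here, which read 25.2 and 21.2 in the zic1 arrays against 1.00, 0.835 and 0.824 in controls (26.2-fold). Foxo3.L (1.34 ± 0.13), pdk4.S (1.26 ± 0.11), gabarapl1.S (1.28 ± 0.13) and both probe sets of sesn1.L (1.88 and 1.61) were past the threshold. FoxO factors regulate the last 3 in other systems. The hypothesis that FoxO targets rise as a class was tested on 30 other such genes. Their median log2 difference was -0.0345 (spread of the median -0.138 to 0.0693), which argues against a rise of these 30 genes as a set. Members went both ways, for example sesn2.L (0.44) and irs1.L (0.39) up and ddb1.S (-0.47) and cat.2.L (-0.38) down. Without absolute signal, undetected genes could not be told from unchanged ones.

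Controls 1 and 2 stood apart from the other 3 arrays in 17 probe sets, at least 2-fold above all of them, against 79 for the zic1 pair and at most 2 for any other pair. Another probe set without a symbol read 27.1 and 27.7 there against 0.774 to 1.00 elsewhere, and mt4.L, cyba.L, b4galt5.L and ptgs1.S were among the rest.

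The first pattern weighed is the rise of mesoderm genes in explants meant to be ectoderm. The test took it that abundant transcripts of mesoderm cells carried along would have risen too. The median over 31 such genes was 0.0233 (spread of the median -0.0187 to 0.0653), but many of these are structural genes of muscle, and the test also needed actc1, which had no probe set. With acta1.S and acta2.L (-0.07 and 0.02) in its place, a choice made afterwards and first used here, the same rule would have excluded mesoderm cells. Among early mesoderm genes wnt8a.L (1.04) and evx1.L (1.01) were past the threshold, while chrd.1.S (0.34), not.L (0.35), not.S (0.32), tbx6.L (0.26), tbxt.S (0.15), mespa.L (0.03), meox2.S (0.02), msgn1.L (0.01), pcdh8l.S (-0.0042), mespa.S (-0.18) and cdx4.L (-0.29) were not, so these genes did not move together. The panel stayed far below the myod1.S rise of 2.86, but without absolute signal an undetected gene would also show no difference. The panel therefore does not decide whether mesoderm cells were present. Without actc1 or absolute signal, such cells and a response of these genes to zic1 cannot be told apart from the array values. The series design also names a check for mesoderm by actin primers, which is not part of those values.

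The second pattern is the lower level of ribosomal protein genes. A trend in abundant transcripts in general may account for part of it: 88 other abundant transcripts had a median of -0.0895 (spread of the median -0.135 to -0.0437), lower than other genes by camera (p = 0.00758; p = 0.317 with an estimated correlation). That median lies above the -0.2 that such a trend was taken to need and is not clearly above the -0.1 taken to exclude it. Without absolute signal, abundance could not be measured, and a trend and a change in ribosomal transcripts cannot be told apart.

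The third pattern is the split of the arrays. Zic1 replicate 1 and controls 1 and 2 shared 788 to 944 exactly equal values per pair, and the other pairs 35 to 73, which is consistent with separate processing of that set of 3 arrays. Zic1 replicate 2 and control 3, the arrays left over, shared 43. Separate processing would not make the differences recur, and over 15490 probe sets the differences within the 3 arrays and between the remaining pair, which share no array, correlated at 0.618 (Pearson; 0.507 Spearman; genes are not independent replicates). The 5 arrays allow 10 splits into 2 and 3, too few for a share under 0.05; 1 of them, the real one, gave as many as 219, and the highest other gave 1. On the second count the real split gave 1128, controls 1 and 2 against the rest 565 and controls 2 and 3 against the rest 454, with 3238, 1984 and 1684 at an unadjusted p under 0.05.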
